A study of Homo sapiens with 7 samples.

How the data were processed

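The series profiled microRNAs (miRNAs) by small RNA sequencing in tumours that grew after SKOV3 cells, a human ovarian adenocarcinoma cell line, were injected into the peritoneal cavity of nude mice. The labels put 4 tumours in a non-stressed group and 3 in a group stressed by physical restraint, and each tumour has a library of its own. The labels do not say whether each tumour came from a separate mouse, so the p-values measure the spread between these tumours.

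Each deposited file held 1 normalised signal value per mature human miRNA for 1 library, per the file headers, and the 7 files listed the same 986 names. FastQC, BWA and limma, and the builds hg19 and GRCh37, are named without roles or versions, per the submitters' processing notes. The counting tool, the miRNA annotation and the normalisation are not given in the sources used here. The values themselves showed part of it. In every library all values were whole multiples of 1 step, within 0.001 of a step, and the smallest value above 0 was 5 steps. The steps ran from 0.669 to 1.42, and their inverses (0.704 to 1.49) lay close to median-of-ratios size factors computed from the recovered multiples (0.705 to 1.50). The deposited signal therefore looks like read counts divided by 1 size factor per library, with counts under 5 listed at 0. A value of 0 would then mean fewer than 5 reads rather than none. If 1 step is 1 read, the libraries held 4942080 to 10961700 miRNA reads. The alignment was to human builds and the tissue holds mouse cells, and many mature miRNAs have the same sequence in human and mouse, so a value can contain reads of host cells.

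Names with identical values in all libraries and values above 0 in at least 3 of them were kept once, which left 971 names. The 15 names left out include miR-199b-3p, kept as miR-199a-3p, and miR-365b-3p, kept as miR-365a-3p. A miRNA was tested when its value was at least 10 in at least 3 libraries, which lies above the smallest listed value of each library and was chosen once the unit was known. This left 647 miRNAs that held 99.99% of the summed signal. The groups were compared with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a variance trend and empirical Bayes moderation, and p-values were adjusted by Benjamini-Hochberg (BH). Fold changes are stressed minus non-stressed on the log2(value + 1) scale. This understates changes of low miRNAs listed above 0 in all libraries, and where some libraries list 0 the size of the change depends on the number added and can be overstated. The design written before the data were examined assumed counts, with a count-based filter and list tests on log2 CPM, and foresaw this limma test for normalised values. Count-model tests and voom weights were not used, since the deposited values are not counts and the reads behind them rest on the assumption that 1 step is 1 read.

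Before the data were examined, 27 lists of mature miRNAs were also fixed (families, genomic clusters, pathways, markers of other cell types, and fragments of other non-coding RNA that carry miRNA names). The 26 lists with at least 2 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, all in limma, with BH adjustment over the lists. Shares of the library total were compared for 10 lists by a two-sided exact permutation test over the 35 ways to pick 3 of 7 libraries, whose smallest possible p is 0.0286. The miRNAs named were taken from the 12 higher and the 12 lower with the smallest p, the 10 with the highest mean value, and up to 4 tested members of each list with the highest mean value. Others that are named were chosen after their values were seen: miR-132-3p and miR-132-5p, miR-133a-5p, miR-499a-5p, miR-941 and let-7c-5p. The alternatives tried were 3 other scalings, other filters and pseudocounts, variance settings, sample weights, a replicate block, and leaving out each library.

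The test was tried on normally distributed log2 values simulated with the means and moderated variances of these 647 miRNAs, of which 200 were changed. It recovered 22 of 67 miRNAs changed 2-fold, 49 of 67 changed 4-fold and 60 of 66 changed 8-fold, and it called 6 of the 447 unchanged miRNAs. With fewer changed miRNAs the recovery would be lower, since the BH threshold depends on how many change. The draws were independent between miRNAs and took the moderated variances as the true ones. They therefore lack variation that miRNAs share between libraries, and recovery in the real data may be lower. In the data the median standard error of a log2 fold change was 0.39. Library depth beyond the recovered multiples is unknown, so no counting intervals are given. Genomic coordinates are not printed, because the reference used here (GRCh38.p14) is a later build than those named by the submitters. That reference served only to find which miRNA genes neighbour each other.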

Results

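Small RNA libraries were compared from 7 SKOV3 xenograft tumours of nude mice, 4 from non-stressed animals and 3 from animals under restraint stress, a procedure in which the mouse is held in a ventilated tube. The recovered read totals averaged 6832670 ± 1395358 (SD, n = 4) in non-stressed and 8179380 ± 2954844 (SD, n = 3) in stressed tumours, and ran from 4942080 to 10961700, a difference within the spread between libraries (two-sided exact permutation p = 0.371). The libraries listed 683 to 835 miRNAs above 0. The number did not separate the groups, at 754 ± 57.5 (SD, n = 4) against 753 ± 70.5 (SD, n = 3; exact permutation p = 1).

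Of the 10 miRNAs with the highest values in each tumour, 8 were the same in all 7 tumours. The 10 highest of each tumour took 58.7 ± 3.5% of the signal in non-stressed tumours (SD, n = 4) and 61.2 ± 2.6% in stressed tumours (SD, n = 3; exact permutation p = 0.371). The highest by mean share over the tumours was miR-199a-3p, which shares its reads with the identical miR-199b-3p, is known from fibroblasts and other mesenchymal cells, and made up 16.2% of the signal on average. It was followed by miR-21-5p, a miRNA raised in many carcinomas, at 7.43%, miR-199a-5p at 7.31% and the HOX-embedded miR-10a-5p at 6.06%. The others among the 10 highest by mean share were miR-99a-5p and miR-26a-5p, miR-27b-3p, and the let-7 members let-7a-5p, let-7f-5p and let-7i-5p. The values of miR-199a-3p were 1135520 ± 531852 in non-stressed (SD, n = 4) and 1287450 ± 299392 in stressed tumours (SD, n = 3), a log2 fold change of 0.30 ± 0.40 (SE). For miR-21-5p the log2 fold change was 0.14 ± 0.22 (SE), and for let-7a-5p it was 0.02 ± 0.21 (SE). With 1 tumour left out these ran from -0.03 (without non-stressed tumour 1) to 0.51 (without non-stressed tumour 3) for miR-199a-3p. They ran from 0.02 (without stressed tumour 1) to 0.28 (without stressed tumour 2) for miR-21-5p and from -0.11 to 0.14 (without non-stressed tumours 2 and 3) for let-7a-5p.

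The main comparison asked which miRNAs differ in tumours of stressed mice. Of the miRNAs with higher values in stressed tumours, the smallest p belonged to miR-4510 (log2 fold change 0.94), miR-34c-5p (1.03), miR-3059-5p, which was listed at 0 in 3 tumours, miR-27a-5p (1.25) and miR-212-5p (1.26). Of those with lower values, it belonged to miR-642a-5p (-1.22), miR-365a-3p (-0.73) and miR-5701 (-1.41). None of these, nor any other miRNA, passed the threshold. Of the 647 tested, 0 reached a BH-adjusted p of 0.05 in limma, the smallest adjusted p was 0.978, and 29 had an unadjusted p under 0.05, where 32.4 would be expected by chance. Of these 29, 20 had higher and 9 had lower values in stressed tumours, whereas 303 of all tested miRNAs were higher and 344 lower. With 1 tumour left out, the 29 ran from 12 (without stressed tumour 1) to 41 (without non-stressed tumour 4). The count was 15 without stressed tumour 2 and 11 under library total rescaling. The groups' values did not overlap for 43 miRNAs, or 6.65%, and chance gives 5.71%. The median 95% interval of a fold change reached 1.88-fold to either side of its estimate, and for 226 miRNAs (34.9%) the whole interval lay within 2-fold of no change. Larger differences of the remaining miRNAs were not excluded by these libraries.

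Among the miRNAs with the smallest p, all of them short of the adjusted threshold (adjusted p = 0.978 in limma for each), several of the higher ones belong together. Both arms of miR-212, a product of a CREB-responsive gene that it shares with miR-132, were at about 2 times their non-stressed level. The value of miR-212-5p was 467 ± 194.8 in non-stressed tumours (SD, n = 4) and 1125 ± 549 in stressed tumours (SD, n = 3), a log2 fold change of 1.26 ± 0.42 (SE), and that of miR-212-3p was 0.98 ± 0.33 (SE). The abundant miR-99a-5p stood at 223345 ± 46777 (SD, n = 4) against 323212 ± 3335 (SD, n = 3), a log2 fold change of 0.56 ± 0.19 (SE). The passenger strand of let-7c, whose gene lies beside that of miR-99a, had a log2 fold change of 0.92 ± 0.34 (SE). Its far more abundant other strand, let-7c-5p, was at 0.28 ± 0.18 (SE), and miR-125b-5p was at 0.55 ± 0.20 (SE). The p53-activated miR-34c-5p was at 408 ± 82.4 (SD, n = 4) against 875 ± 383 (SD, n = 3), a log2 fold change of 1.03 ± 0.33 (SE). For miR-27a-5p the log2 fold change was 1.25 ± 0.42 (SE), and for the far more abundant miR-27a-3p of the same hairpin 0.23 ± 0.31 (SE). That of miR-224-5p was 0.98 ± 0.34 (SE), that of miR-7974 0.95 ± 0.34 (SE), and that of miR-33b-3p, made from an intron of SREBF1, 0.93 ± 0.34 (SE). Without stressed tumour 2 that of miR-7974 was 0.61. The smallest p of all, 0.00646 before adjustment, belonged to the scarce miR-4510, at 32.8 ± 4.6 (SD, n = 4) against 63.5 ± 3.8 (SD, n = 3). The last of the 12, miR-3059-5p, was listed at 0 in 3 of the 4 non-stressed libraries and at 8.76 in the other, against 12.8 to 30.1 in the stressed libraries. The values of the groups did not overlap for 11 of these 12 miRNAs, against 6.65% of all tested. The 12 were picked for the smallest p, so that count is no separate support.

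The 12 lower miRNAs with the smallest p included the hepatocyte miRNA miR-122-5p, at 1504 ± 944 (SD, n = 4) against 385 ± 146 (SD, n = 3), a log2 fold change of -1.68 ± 0.67 (SE, limma adjusted p = 0.978). Non-stressed tumour 2, at 313, lay within the stressed range for it. The value of miR-365a-3p, which shares its reads with miR-365b-3p, was 5087 ± 1145 (SD, n = 4) against 3057 ± 597 (SD, n = 3), a log2 fold change of -0.73 ± 0.25 (SE). For miR-642a-5p the log2 fold change was -1.22 ± 0.40 (SE), for miR-5701 -1.41 ± 0.51 (SE), for miR-550a-3p -1.03 ± 0.42 (SE), and for miR-326, made from an intron of the beta-arrestin gene ARRB1, -1.40 ± 0.66 (SE), which was -0.88 without stressed tumour 2. Smaller differences were measured for miR-197-3p (-0.72), miR-7-1-3p (-0.61), miR-324-5p (-0.56) and miR-1296-5p (-0.51 on the log2 scale). The snoRNA-derived miR-1291 stood at 48.2 ± 13.8 (SD, n = 4) against 27.3 ± 2.8 (SD, n = 3). The lowest of the 12, miR-5582-3p, was listed at 0 in 2 of the 3 stressed libraries and at 5.84 to 20.1 in the non-stressed ones. The values of the groups did not overlap for 5 of these 12, which were likewise picked for the smallest p.

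**Figure D1:**
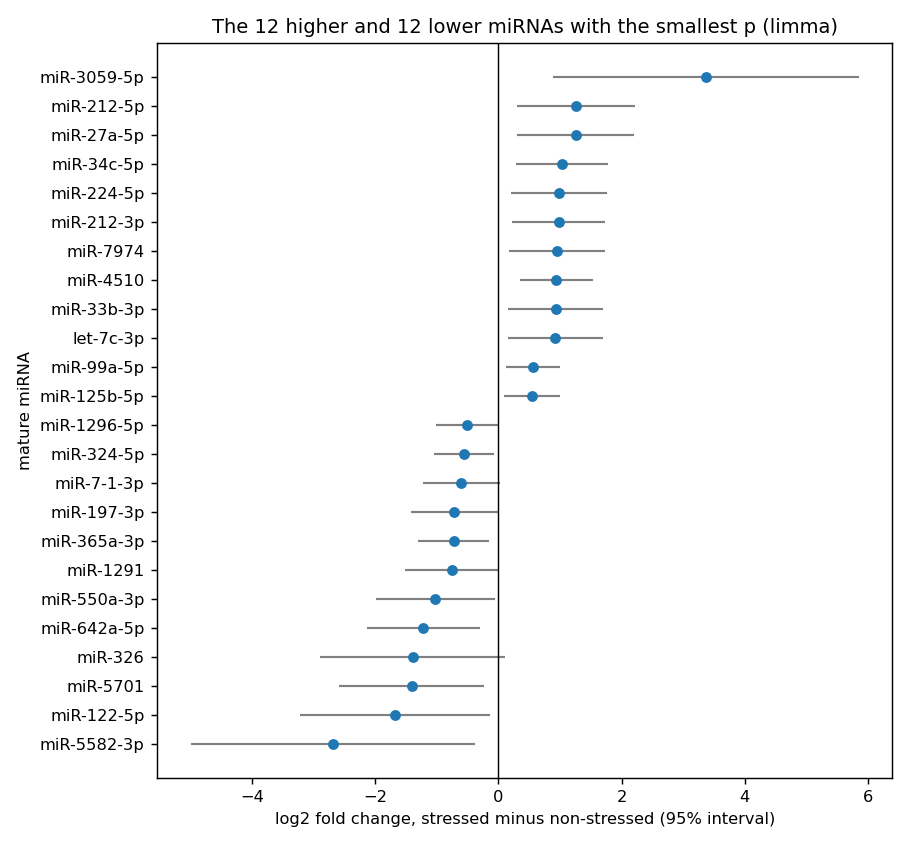
The horizontal axis gives the log2 fold change (stressed minus non-stressed, limma on log2(value + 1), 4 against 3 tumours), points are estimates and lines are 95% intervals that are not adjusted for the 647 tests. The widest intervals belong to miR-3059-5p and miR-5582-3p, which were listed at 0 in several libraries, and no miRNA shown passed an adjusted p of 0.05.

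The tumour-related families were examined as lists. No member of any of the 27 lists passed BH over all tested miRNAs in limma. Adjusted over the list alone, 0 members passed in 26 lists, and the only member tested in the liver list, miR-122-5p, had a p of 0.0366. In camera 0 of 26 lists passed and 6 had an unadjusted p under 0.05. With 1 tumour left out, the median of 25 of the 26 lists moved by over 1.5 times or changed sign, and that of 14 changed sign. The epithelial miR-200 family had 5 of 7 tested members higher and 2 lower (median log2 fold change 0.21, camera adjusted p = 0.691), and its members varied within groups. Its median was -0.25 without stressed tumour 1 and 0.75 without stressed tumour 2, where camera made a call (adjusted p = 0.0327, and 0.529 with an estimated correlation). For example, miR-200c-3p was at 50866 ± 37283 in non-stressed (SD, n = 4) and 57152 ± 17954 in stressed tumours (SD, n = 3). Of the proliferation-linked miR-17-92 and paralogous clusters, 11 of 15 members were higher and 4 lower (median 0.15, camera adjusted p = 0.380), with miR-92a-3p at a log2 fold change of 0.31 ± 0.23 (SE) and miR-17-5p at 0.36 ± 0.31 (SE). Without stressed tumour 2 these were 0.10 and 0.15, and without non-stressed tumour 3 that of miR-17-5p was 0.13. Under library total rescaling the medians of the miR-200 and miR-17-92 lists were 0.07 and 0.00909, and under upper quartile rescaling 0.30 and 0.24. The let-7 family, known to restrain growth, had 3 of 9 members higher and 6 lower, with a median of -0.04 that turned to 0.05 under upper quartile rescaling (camera adjusted p = 0.921), and to 0.10 and 0.02 without non-stressed tumour 3 and stressed tumour 2. In the family of miR-15 and miR-16, which targets cell cycle genes, 6 of 7 members were lower, with miR-16-5p at -0.27 ± 0.18 (SE) and miR-195-5p at -0.29 ± 0.20 (SE). The camera adjusted p of this family was 0.113, and it was 0.874 with an estimated correlation.

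Of the miR-23, miR-24 and miR-27 clusters, 7 of 8 members were higher (median 0.20, camera adjusted p = 0.113), although the abundant miR-27b-3p and miR-24-3p differed by log2 fold changes of 0.05 ± 0.23 (SE) and 0.17 ± 0.27 (SE). With 1 tumour left out these ran from -0.10 (without non-stressed tumour 1) to 0.19 (without stressed tumour 2) and from -0.01 to 0.37 (without non-stressed tumours 1 and 3). The median was 0.06 under library total rescaling, 0.29 under upper quartile rescaling and 0.00495 without non-stressed tumour 1. It was 0.41 without non-stressed tumour 3 and 0.31 without stressed tumour 2, each with a camera call (adjusted p = 0.0156 and 0.0364, and 0.915 and 0.788 with an estimated correlation). The HOX-embedded miR-10 and miR-196 list had 5 of 6 members higher (median 0.33, camera adjusted p = 0.180), among them miR-10b-5p at 0.46 ± 0.21 (SE). With 1 tumour left out the median of this list ran from 0.10 (without stressed tumour 2) to 0.48 (without stressed tumour 3). All 3 members of the cluster of miR-221 and miR-222 were lower (median -0.30, camera adjusted p = 0.483). The cluster of miR-183, miR-96 and miR-182 (median 0.19, camera adjusted p = 0.531), the miR-29 family (median -0.29, camera adjusted p = 0.726), the miR-181 family (median 0.09 but mean -0.03, camera adjusted p = 0.726) and the miR-30 family (median 0.03 but mean -0.02, camera adjusted p = 0.877) gave no call. In the miR-29 family the most abundant member by far, miR-29a-3p, was higher (0.35 ± 0.19, SE), and the other 2 were lower. Under library total rescaling the medians of the miR-181 and miR-30 families were -0.05 and -0.11. Without non-stressed tumour 1 the medians were -0.17 for miR-181, -0.03 for miR-30 and -0.19 for the miR-183 cluster. Without stressed tumour 1 they were -0.08 for miR-181 and -0.08 for miR-30, and without non-stressed tumour 2 that of miR-30 was -0.00750. In the DLK1-DIO3 cluster, an imprinted cluster at 14q32, 15 of 30 tested members were higher and 15 lower (median 0.03, and -0.07 under library total rescaling, camera adjusted p = 0.921, with a mean of -0.08 and a test direction opposite to the median). Its median was -0.06, -0.07 and -0.04 without non-stressed tumours 3 and 4 and stressed tumour 2. Of the list fixed for the primate-specific C19MC cluster, which does not hold every arm of the cluster, 3 members were tested and all 3 were lower (median -0.40, camera adjusted p = 0.448), with miR-516a-5p at 1811 ± 1121 (SD, n = 4) against 1389 ± 826 (SD, n = 3). Without stressed tumour 3 the median of this list was 0.16.

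Pathway lists that fit a stress treatment gave no call either. In the NF-kB and inflammation list 8 of 10 members were higher, with a median log2 fold change of 0.31. Its camera adjusted p was 0.113, and 0.874 with an estimated correlation. Without non-stressed tumour 2 the median was 0.35 and camera made a call (adjusted p = 0.0373, and 0.749 with an estimated correlation). The median of this list was 0.19 without non-stressed tumour 4. Of its members, miR-146b-5p was at 96143 ± 50578 (SD, n = 4) against 130954 ± 50020 (SD, n = 3), and the 3 members with an unadjusted p under 0.05 were miR-125b-5p, miR-212-3p and miR-132-3p, the last of them named after its value was seen. Of the stress-hormone-linked list 6 of 8 members were tested, of which 2 were higher and 4 lower (median -0.21, camera adjusted p = 0.726), with miR-29a-3p at 0.35 ± 0.19 (SE) and miR-15b-5p at -0.19 ± 0.23 (SE). Without non-stressed tumour 1 miR-15b-5p was at -0.07. The median of the list was 0.02 without non-stressed tumour 1 and 0.16 without stressed tumour 2. The p53-regulated list had 3 of 8 tested members higher (median -0.06, and 0.03 under upper quartile rescaling, camera adjusted p = 0.877), with medians of 0.03 and 0.00970 without non-stressed tumours 1 and 2. The hypoxia list had 2 of 6 higher (median -0.09, camera adjusted p = 0.726), and its best-known member, miR-210-3p, was at 4992 ± 936 (SD, n = 4) against 4475 ± 907 (SD, n = 3).

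A xenograft also holds host blood, vessels, stroma and adjacent tissue, and markers of such cells were examined as lists. The skeletal and cardiac muscle list (miR-1-3p, miR-133a-3p, miR-206 and others) took 0.697%, 1.27% and 0.751% of the signal in non-stressed tumours 2 and 4 and stressed tumour 3, and 0.00638% to 0.0199% in the other 4 tumours. Of its 5 tested members 1 was higher and 4 lower in stressed tumours (camera adjusted p = 0.726), and the median of -1.18 was 0.34 without non-stressed tumour 4, 0.69 without stressed tumour 2 and -3.49 without stressed tumour 3. The value of miR-1-3p was 27293 to 79681 in those 3 libraries and 146 to 616 in the others, and its log2 fold change between the groups was -1.18 ± 2.58 (SE), from -3.49 without stressed tumour 3 to 0.50 without stressed tumour 2. The fibroblast and smooth muscle list took the largest share, 23.8 ± 5.5% in non-stressed (SD, n = 4) and 26.3 ± 3.0% in stressed tumours (SD, n = 3; exact permutation p = 0.571), with a median log2 fold change of 0.06 but a mean of -0.01 (camera adjusted p = 0.877). Nearly all of that share was miR-199a-3p (16.2% on average) and miR-199a-5p (7.31%), so it mainly follows miR-199a, while miR-143-3p held 0.80%. Of the 11 tested members 6 were higher and 5 lower, with miR-199a-5p at 0.46 and miR-143-3p at -0.19. The endothelial list was at 0.775 ± 0.313% (SD, n = 4) against 0.708 ± 0.211% (SD, n = 3; exact permutation p = 0.83), with a median log2 fold change of 0.09 (camera adjusted p = 0.877). Under library total rescaling the fibroblast and endothelial medians were -0.08 and -0.05. The fibroblast median was -0.10 without non-stressed tumour 1, and the endothelial one -0.10 without non-stressed tumour 3 and -0.11 without stressed tumour 3. All 5 erythroid members (among them miR-451a, log2 fold change -0.45 ± 0.44, SE) and all 4 myeloid and pan-haematopoietic members (among them miR-223-3p, -0.53 ± 0.39, SE) were lower in stressed tumours. The myeloid members are both arms of miR-142 and miR-223, and the erythroid ones both arms of miR-144 and miR-486 with miR-451a. Arms of 1 hairpin are not independent, so these counts overstate the agreement. Without non-stressed tumour 1 the erythroid miR-144-5p was at 0.08. With 1 tumour left out miR-451a ran from -0.90 (without stressed tumour 2) to -0.18 (without stressed tumour 1) and miR-223-3p from -0.87 to -0.34 (without non-stressed tumours 4 and 2). The camera adjusted p of the lists were 0.403 and 0.113, the latter 0.874 with an estimated correlation. The erythroid median of -0.41 was -0.90 without stressed tumour 2, with a camera call (adjusted p = 0.0327, and 0.529 with an estimated correlation), and -0.06 without stressed tumour 3. The myeloid median of -0.50 was -0.71 without non-stressed tumour 4, with a camera call (adjusted p = 0.00667, and 0.873 with an estimated correlation), and -0.30 without non-stressed tumour 2. The shares were 0.344 ± 0.084% against 0.249 ± 0.161% for the erythroid list (SD, n = 4 and 3, exact permutation p = 0.371) and 0.0451 ± 0.0245% against 0.0271 ± 0.0033% for the myeloid list (exact permutation p = 0.400).

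The liver list, nearly all miR-122-5p, had the lowest exact permutation p of the 10 shares, at 0.0218 ± 0.0136% in non-stressed (SD, n = 4) against 0.00518 ± 0.00220% in stressed tumours (SD, n = 3, exact permutation p = 0.114, adjusted 0.914). The pancreas list, led by miR-148a-3p and miR-375-3p, which are also epithelial miRNAs, took 1.35 ± 0.78% (SD, n = 4) against 1.25 ± 0.74% (SD, n = 3, exact permutation p = 0.83), with a median log2 fold change of 0.36 (camera adjusted p = 0.535) that was -0.16 without stressed tumour 1 and 1.41 without stressed tumour 2. Its abundant members miR-148a-3p and miR-375-3p were at 0.07 and -0.01. The scarce miR-217-5p (0.66) and miR-216b-5p (1.75), whose values reached only 44.2 and 30.1, raised the median. The neural list took 1.04 ± 0.12% against 1.06 ± 0.20% and the lymphoid list 0.00513 ± 0.00364% against 0.00535 ± 0.00058% (SD, n = 4 and 3, exact permutation p = 0.914 for each). Their camera adjusted p was 0.535 for each, with medians of 0.05 (neural, and -0.09 under library total rescaling) and 0.35 (lymphoid). Fragments of other non-coding RNA that carry miRNA names, a sign of RNA composition, took 0.277% to 3.62% in non-stressed and 0.562% to 1.82% in stressed tumours (exact permutation p = 0.83). Most of it was miR-1246, which reached 283765 in non-stressed tumour 3 and 124970 in stressed tumour 2. In that list 15 of 19 tested members were lower in stressed tumours (median log2 fold change -0.38, camera adjusted p = 0.113, and 0.874 with an estimated correlation). The median was 0.11 without non-stressed tumour 3 and -0.67 without non-stressed tumour 4, the latter with a camera call (adjusted p = 0.000897, and 0.873 with an estimated correlation).

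**Figure D2:**
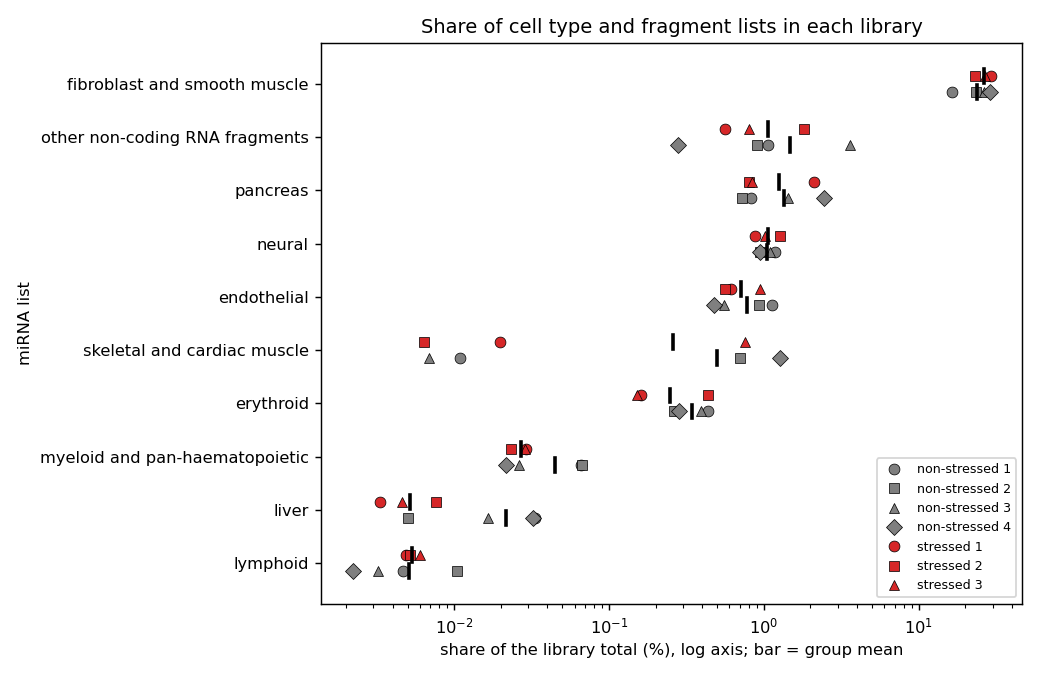
The horizontal log axis gives the share of each library's summed signal in percent, the vertical axis the list, grey and red symbols the non-stressed and stressed tumours by replicate, and black bars the group means. The muscle list splits into 3 libraries at 0.697% to 1.27% and 4 at 0.0199% or less, with tumours of each group on either side.

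Taken over both groups, tumours of the same group were not more alike than tumours of different groups. Over the tested miRNAs the Spearman correlation between libraries ran from 0.926 to 0.963. Its mean was 0.942 within groups and 0.948 between groups, a difference of -0.00615 (one-sided exact permutation p = 0.943 for a larger value). Pairs of stressed tumours ran from 0.946 to 0.960 and pairs of non-stressed tumours from 0.926 to 0.941. Pairs across the groups ran from 0.933 to 0.963. The first principal component held 33.1% of the variance. It placed the 3 libraries rich in muscle miRNAs at -13.1 to -9.25 and the pair richest in miR-1246 at 17.2 and 18.4, each set with tumours of both groups. The muscle miRNAs and miR-1246 were among the values behind the component, so this placement is no separate evidence of such a split.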

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

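The comparison with other splits by the count of unadjusted calls was set before its result was seen, and the other tests here were chosen afterwards. Among 130 values checked in the 4 non-stressed tumours, 5 had 1 tumour far from the other 3, and chance alone gives about 1 in 20. Non-stressed tumour 4 had the low value of miR-221-3p (16097, against 33098 to 35987 in the other 3) and of miR-503-5p (781 against 895 to 903), and it was the only one of these 4 with miR-3059-5p above 0 (8.76). Non-stressed tumour 1 had the high value of miR-195-5p (981 against 834 to 856). Non-stressed tumour 2 had the high value of miR-411-5p (1610 against 975 to 1031).

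The muscle miRNAs were high in non-stressed tumours 2 and 4 and stressed tumour 3. The lowest of these 3 libraries exceeded the highest of the other 4 by 44.3 times for miR-1-3p and 58.4 times for miR-206, and the smallest gap over 5 muscle miRNAs was 17.6 times (miR-133a-3p). These libraries were picked on the same miRNAs, so the gap cannot decide whether host skeletal muscle in the tissue is the source, and miR-499a-5p, also in the list, was at 113 to 513 in these 3 and 117 to 303 in the others. Library scaling is argued against, since the gap of miR-1-3p was 27.5 times the largest ratio between libraries of the factors of the 3 other scalings. The steps of the deposited values differed at most 2.12-fold between libraries, also far below that gap. Carry-over from 1 of these libraries into the others is argued against, because the ratio of miR-206 to miR-1-3p differed 7.83-fold between the 3. Host muscle and muscle-like expression in the tumour cells stay open, and no biological explanation was tested.

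Over all splits of the 7 tumours into 4 and 3, at least the real 29 unadjusted calls came from 17 of 35 splits (highest other 73), so chance cannot be excluded for that count. The real count of 0 adjusted calls is reached by 35 of 35 splits whatever the data (highest other 6), which decides nothing. The split with 6 adjusted calls sets the 3 muscle-rich tumours against the rest, and it called miR-1-3p, miR-133a-3p, miR-133a-5p, miR-133b, miR-206 and miR-381-3p. All of these but miR-381-3p are the muscle miRNAs on which the 3 tumours stood apart, so these calls restate how the tumours were picked. That split had 16 unadjusted calls, fewer than the real 29. Whether a highest count of 6 adjusted or 73 unadjusted calls exceeds chance was not tested.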

How the results depend on the processing

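No miRNA passed the threshold in limma under any of the 23 alternatives, and the 24 leading miRNAs kept their sign wherever they were tested. These 24 were picked for the smallest p in the same libraries. That choice favours kept signs and small moves, so neither supports them. Of the alternatives 5 were chosen after seeing the data: all names kept, without the 3 muscle-rich libraries, a muscle covariate, zeros as missing (which gives no list test) and no variance trend. The smallest limma adjusted p was 0.256 (miR-122-5p, without non-stressed replicate 2). Of 115 named miRNAs 55, and of 26 list medians 16, took the other sign under at least 1 alternative, and none of these miRNAs passed. With 1 library left out, 2 of the 24 leading miRNAs (miR-7974, miR-326) and 87 of all 115 named moved by over 1.5 times or to the other sign. The 29 unadjusted calls became 11 under library total rescaling, which moved the median log2 fold change of all miRNAs from -0.02 to -0.16, and 10 when the host cell lists were left out and totals rescaled, a drop that the rescaling gives without leaving them out. They became 12 and 15 without stressed replicates 1 and 2, and 33 and 41 without non-stressed replicates 3 and 4. The 0 list calls of camera became 1 with a minimum value of 100 (NF-kB and inflammation, adjusted p = 0.0475), 1 with sample weights (miR-23, miR-24 and miR-27, adjusted p = 0.0216) and 1 without the 3 muscle-rich libraries (other non-coding RNA, adjusted p = 0.0189). They were 0 to 3 with 1 library left out: 1 without non-stressed replicate 2 (NF-kB), 1 without non-stressed replicate 3 (miR-23, miR-24 and miR-27), 2 without non-stressed replicate 4 (other non-coding RNA, myeloid) and 3 without stressed replicate 2 (miR-200, miR-23 with miR-24 and miR-27, erythroid). The replicate block gave 0 miRNA calls and 2 camera list calls (other non-coding RNA, myeloid). With an estimated correlation and with fry, added under the alternatives after seeing the data, the list calls were 0 in the main setting and in every alternative with list tests. The 12 camera calls had adjusted p of 0.529 to 0.961 with an estimated correlation and 0.538 to 0.990 in fry. The cause of the camera calls was not tested. The block drops non-stressed replicate 4, and the labels do not say whether the numbers pair the tumours. Same-numbered deviations correlated at 0.01, -0.16 and -0.26, and each stressed tumour correlated better with another number. Each was set against the best of the other non-stressed tumours, so these few values cannot decide whether the numbers pair the tumours. The planned edgeR, DESeq2, limma-voom and TMM alternatives were not run: the deposited values are not counts, and the whole multiples in them start at 5 steps, so that 1 step is 1 read is an assumption. Count tests on those multiples remain possible. Taking the largest of duplicate names was not run either, since no name occurs more than once in a file. If 1 step is 1 read, reads under 5 are listed at 0, which would limit scarce miRNAs such as miR-3059-5p.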

Other observations

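The test of scalings was set before its result was seen, and the other tests here were chosen afterwards. The assignment of miRNAs to gene clusters was also corrected after a first count of splits, which had likewise left chance open, had been seen. The genes of miR-132 and miR-212 lie side by side, and all 4 of their arms had higher mean values in stressed tumours, with none past the threshold. The log2 fold change was 0.85 for miR-132-3p, 1.06 for miR-132-5p, 0.98 for miR-212-3p and 1.26 for miR-212-5p. The mean log2 value of the 4 arms was 9.29 ± 0.55 (SD, n = 4) in non-stressed and 10.32 ± 0.46 (SD, n = 3) in stressed tumours (two-sided exact permutation p = 0.0857). The neighbouring genes of miR-99a and let-7c had a mean log2 fold change of 0.54 over their 4 tested arms. Their camera adjusted p over 49 gene clusters was 0.00562, but 0.951 with an estimated correlation and 0.998 in fry.

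The gene of miR-132 and miR-212 is known to respond to CREB, so a higher output under stress may be put as a hypothesis, found and tested on the same data. Among 49 gene clusters with at least 3 tested arms, this one had the mean moderated t farthest from 0 (2.80), with a camera adjusted p of 7.54e-05 that was 0.951 with an estimated correlation and 0.998 in fry. Some cluster lay as far from 0 in 12 of 35 splits of the tumours (highest other 11.2), and in 9 of 35 with the muscle cluster left out, so chance cannot be excluded. The authors' scaling is argued against, as the smallest mean log2 fold change over 3 other scalings was 0.90 (library total), beside 1.04 with the deposited values. Of the 3, median-of-ratios rescaling nearly repeats the deposited scaling and is no separate check. With 1 library left out the smallest mean was 0.79 (without stressed replicate 2). The cluster was picked for its moderated t in these same libraries, which favours small moves, so this cannot exclude a single deciding library. An effect of stress stays open.

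The ratio of the mesenchymal miR-199a-3p to miR-941, known only from humans, ran from 80.0 to 312 in non-stressed and from 120 to 505 in stressed tumours. The log2 difference was 0.53 (two-sided exact permutation p = 0.514).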
